A study of Homo sapiens with 4 samples.

How the data were processed

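Ribosome-protected fragments (Ribo-seq, sequencing of the mRNA pieces that ribosomes cover) were measured in HEK293 cells, an established human embryonic kidney line. The labels define 4 groups by genotype (wild type or RPL4 mutant) and treatment (no erythromycin or erythromycin), with 1 library in each. The treatment protocol describes stable lines that express GFP, wild type RPL4 or RPL4 lacking a loop, together with lentiviral short hairpin RNA against RPL4 or a scrambled one. The extraction protocol names cycloheximide and lactimidomycin, which hold elongating or initiating ribosomes in place. The labels do not say which of these conditions each library had, and they give no dose of erythromycin.

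The deposited files hold 1 value in RPKM (reads scaled by transcript length and by the mapped reads of the library) per transcript, as made by the authors. The submitters' processing notes name cutadapt, STAR and the genome build GRCh38, without their roles or versions. The read counter and the annotation release are not given in the sources used here. Each library lists only transcripts above 0, so a transcript absent from a file was read as 0. The files listed 16292 transcripts in at least 1 library and 12243 in all 4. Of the 16292, 16172 were matched to GENCODE release 29, and the other 120 stayed in the tables without a position or coding length.

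The unit was tested on the files. RPKM times coding length is a whole number of reads once the library total is known, and this held for 99.1% to 99.2% of matched transcripts in each library, within 0.001 reads. The totals recovered in this way were 2965243 reads in wild type without erythromycin, 2555613 in wild type with it, 604506 in the mutant without it and 993461 in the mutant with it. The recovered reads made up at least 99.9% of each total. For 216 transcripts the length was solved from the values themselves. For 98 the reads stayed unknown, and 0 of these were among the genes tested.

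Values were analysed as log2(RPKM + 1). Genes with a mean of at least 5 RPKM over the 4 libraries were kept, which left 9612, and each log2 ratio was centred on the median of these genes. The 4 single differences were erythromycin over none in each genotype and mutant over wild type in each treatment. The difference between the erythromycin responses of the genotypes was the mutant ratio minus the wild type ratio. With 1 library per group there is no replicate check for these 5 quantities, so no p is given for them. Genes at or beyond 2-fold were counted. As a yardstick, counts were repeated in 100 simulated draws in which libraries of the real depth differed by counting noise alone. No paired analysis was possible because nothing in the labels links libraries beyond their groups.

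Effects over both arms were tested with limma 3.58.1 (R 4.3.3): log2 values with an additive model of genotype and treatment, a variance trend, and Benjamini-Hochberg adjustment at 0.05. This model has 1 residual degree of freedom, so that the difference between the genotypes' responses serves as the error. It compares 2 libraries with 2 in each direction and is exploratory. Tested on simulated data with 200 changed genes, it called 54.7% of 2-fold and 97.8% of 4-fold changes, with 12 calls among unchanged genes. In data with no change it called 0 of 9410 genes. The simulated libraries held counting noise only, and any drug effect was the same in both genotypes. These rates therefore do not cover spread between cultures or responses that differ between the genotypes.

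A total of 40 gene lists and the rule for naming genes were fixed before the data were examined, as were all choices other than those named below as later additions. The median log2 ratio of a list with at least 5 measured members was placed at its percentile among 10000 random lists of the same size, drawn from the same 20 bins of mean expression. A list is said to stand apart at a percentile of 2.5 or less, or 97.5 or more. This describes these libraries and is not a test against replicates. Of the lists, 35 had enough members, and about 1.8 of these would stand apart by chance in each comparison. For limma, the count of passing genes over all genes tested is given beside the count adjusted over the list alone.

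Genes were named by rule. RPL4 came first. Among genes with a mean of at least 20 RPKM, the rule took the 10 highest and 10 lowest by the weaker response for erythromycin in both genotypes and for the mutant in both treatments. It also took the 5 highest and 5 lowest in each single difference and in the difference of responses, the 3 most abundant measured members of each list, and all members of a list of up to 13 genes where it is the subject. Other genes are marked where they appear, and some genes that the rule takes are not reported here.

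Precision follows from depth. The median number of reads per tested gene was 108, 91, 23 and 40 in the order of libraries above. For a transcript of 1 kb, 3 reads, the most that a count of 0 allows, correspond to 1.01, 1.17, 4.96 and 3.02 RPKM. Ratios carry 95% exact conditional (Clopper-Pearson) counting intervals, shares carry 95% Wilson score intervals, and list medians carry ± the half-width of a 95% interval from counting. The intervals of ratios use reads and library totals without the pseudocount, shifted by the same median as the ratio. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only and no biological spread.

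Alternatives fixed in advance were pseudocounts of 0.1 and 5 RPKM, a mean of at least 1 or 20 RPKM or no filter, no centring, scaling to a common sum, scaling by the sum of genes outside the ribosomal proteins, the mitochondrially encoded genes and the 20 highest, and limma without a term for the other factor. Chosen after seeing the data were thinning all libraries to the shallowest, a filter on at least 20 reads expected in the shallowest library, limma without the variance trend, and random lists matched also on coding length and GC content. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Positions of reads within transcripts were not analysed here.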

Results

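Ribosome footprints were sequenced from HEK293 cells with wild type or mutated RPL4, each without and with erythromycin, a macrolide antibiotic that binds the peptide exit tunnel of bacterial ribosomes. RPL4 encodes a protein of the large ribosomal subunit that lines this tunnel in the cytosolic ribosome. There was 1 library in each of the 4 groups, so no group had a replicate. All 4 are footprint libraries, with none of total mRNA. Differences in footprints can therefore come from mRNA level or from translation, and these were not separated. Wild type libraries held 2965243 reads without and 2555613 with erythromycin, and mutant libraries held 604506 and 993461. Cytosolic ribosomal protein genes took 13.8% (95% Wilson interval 13.7% to 13.8%) and 14.3% (14.2% to 14.3%) of reads in wild type and 11.4% (11.3% to 11.5%) and 11.3% (11.3% to 11.4%) in the mutant. Single differences below are log2 ratios of deposited RPKM plus 1, centred on the median gene, with 95% counting intervals in brackets. The intervals are for the ratio of reads without the added 1 RPKM, centred alike, so at low counts the value can lie off their middle.

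Footprints on RPL4 itself (chromosome 15, 66498015 to 66504883, GRCh38) were fewer in the mutant. Its RPKM was 2515 and 2586 in wild type without and with erythromycin, against 1707 and 1439 in the mutant. The log2 ratio of mutant over wild type was −0.53 [−0.62, −0.45] without and −0.91 [−0.98, −0.83] with the drug, and over both treatments RPL4 fell by 0.71 (SE 0.148, limma, adjusted p = 0.0447). Erythromycin over none gave 0.06 [0.01, 0.10] in wild type and −0.30 [−0.40, −0.20] in the mutant. A transgene copy of RPL4 would be read as RPL4 in these files, so the values check the genotype labels only in part.

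The comparison of wild type cells with and without erythromycin asked which genes changed in footprint level with the drug in cells with unaltered ribosomes. Genes encoded in mitochondrial DNA, which the mitochondrion's own bacteria-like ribosomes translate, were lower with erythromycin. The median log2 ratio of the 7 measured genes was −0.96 ± 0.18, below that of all random lists (percentile 0), and 7 of 7 were below 0. MT-CO1, a core subunit of cytochrome c oxidase, was at 331 RPKM without and 166 with the drug (−0.97 [−1.11, −0.84]). MT-CO2, another subunit of that enzyme, was at 314 and 128 (−1.27), and MT-ATP6 of ATP synthase at 196 and 98.8 (−0.96). MT-ND4L (−1.06), MT-ATP8 (−0.69), MT-ND5 (−0.46) and MT-ND6 (−0.30), subunits of complex I or ATP synthase, were lower by these log2 ratios. MT-ND6 lies on the opposite strand next to MT-ND5, and the files do not separate strands. The other mitochondrially encoded proteins were not analysed here.

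**Figure D1:**
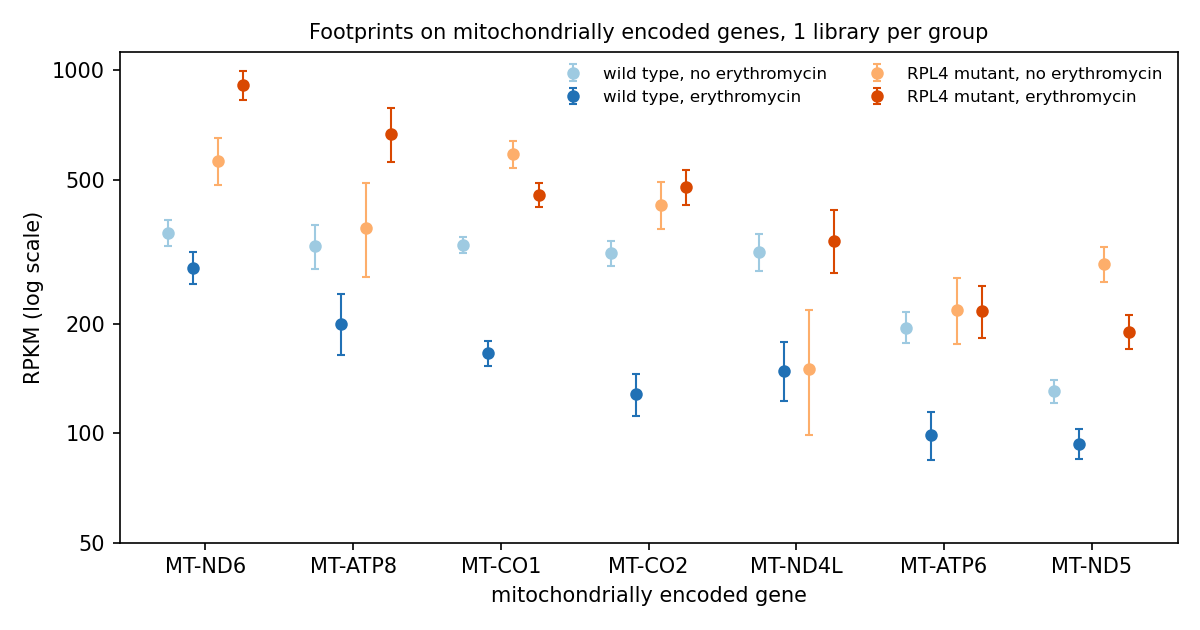
RPKM (log axis) of 7 mitochondrially encoded genes in the 4 libraries, 1 point per gene and library, with bars for the 95% interval from counting. In wild type each gene is lower with erythromycin, as for MT-CO2 at 314 without and 128 with it. In the mutant the genes differ in direction, with MT-CO2 at 426 and 477 and MT-CO1 at 588 and 454.

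Nuclear genes for the same respiratory complexes were slightly lower in wild type with erythromycin. The 56 nuclear-encoded oxidative phosphorylation subunits had a median of −0.18 ± 0.039 (percentile 0), with 42 below 0. COX7C was at −0.17 and COX6A1 at −0.08, while NDUFA1 was above 0 at 0.52. Mitochondrial ribosomal proteins (76 measured) did not stand apart, with a median of −0.04. Replication-dependent histones (48 measured), which package newly made DNA, were lower at −0.18 ± 0.04 (percentile 0.01). HIST1H3B, a gene for histone H3, was at 12365 RPKM without and 10084 with the drug.

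Heat-shock genes and genes of the unfolded protein response were higher in wild type with erythromycin. The 19 cytosolic heat-shock genes had a median of 0.30 ± 0.078 (percentile 100), with 17 above 0. The chaperones HSPA8 (0.45), HSP90AB1 (0.42) and HSP90AA1 (0.30) led the list by abundance. The 21 genes of the unfolded protein response, which restores folding in the endoplasmic reticulum, were higher at 0.30 ± 0.097 (percentile 99.98), with CANX at 0.54 and CALR at 0.37 but SEC61B at −0.30. Other lists of folding factors did not stand apart, with chaperonin and prefoldin at 0.09 (85.5), signal recognition and translocation at 0.06 (77.2), nascent-chain factors at 0.14 (88.9) and mitochondrial chaperones at −0.03 (33.2). Lysosome and autophagy genes (26 measured, median 0.22, percentile 99.6; SQSTM1 0.51, PSAP 0.17, CTSD −0.35), immediate early genes (21, 0.22, 98.9; JUN 0.23, BTG1 0.07, BTG2 −0.52), nonsense-mediated decay factors (14, 0.20, 97.6; EIF4A3 0.30) and ribosome biogenesis factors (58, 0.13, 99.3; NPM1 0.37, FBL 0.23, NOP10 −0.03) were also higher. The call on decay factors ended with a pseudocount of 0.1 RPKM (percentile 97.3), with a mean of at least 20 RPKM (94.7) and in thinned reads (76.8). That on ribosome biogenesis ended with a mean of at least 20 RPKM (95.7) and in thinned reads (92.8).

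Among single genes, DBP, a transcription factor of the circadian clock, was at 25.5 RPKM without and 1894.5 with erythromycin (6.17 [5.90, 6.58]). ITGB2, the integrin beta chain of white blood cells (3.36), IGSF22 (3.16) and GADD45B, a stress-induced growth-arrest gene (2.48), were also higher. MTRNR2L12, a nuclear copy of mitochondrial ribosomal RNA sequence, had 1 read without and 10 with the drug (3.29 [0.74, 8.99]). On the lower side, CCDC151, needed to dock dynein arms in cilia, was at 724 and 40.5 RPKM (−4.11 [−4.37, −3.93]). ANKRD37, a target of hypoxia signalling (−2.03), USP1, a deubiquitinase of DNA repair (−1.85), EBF4 (−1.72) and HIVEP3 (−1.71), both transcription factors, followed. A total of 166 genes were at least 2-fold higher and 148 at least 2-fold lower. Counting noise alone gave 48.9 such genes on average and 64 at most. The total of 314 ranged from 65 with at least 20 reads expected to 1096 in thinned reads.

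In RPL4 mutant cells, the same comparison asked whether the drug moved the same genes when the ribosome is altered. With erythromycin 0 lists stood apart as higher in the mutant, and 7 stood apart as lower. Proteasome subunits, which degrade tagged proteins (30 measured), had a median of −0.20 ± 0.072 (percentile 0.36; PSMB1 −0.30, PSMB2 −0.14). Cytoskeleton genes (23) were at −0.28 ± 0.087 (0.07; ACTB −0.49, TMSB4X −0.21, PFN1 0.02), glycolysis enzymes (15) at −0.28 ± 0.074 (0.525; GAPDH −0.34, ENO1 −0.28, TPI1 −0.03) and aminoacyl-tRNA synthetases (20), which charge tRNAs, at −0.26 ± 0.14 (1.79; FARSA −0.24, HARS −0.11, YARS 0.21). Genes of G2 and M phase (24; −0.23, 1.34; UBE2C −0.37, AURKB −0.01, BIRC5 0.30) and spliceosome and mRNA-binding proteins (32; −0.17, 1.12; SRSF3 −0.26, HNRNPA2B1 −0.18, YBX1 0.03) were lower too. Interferon-stimulated genes (7) were at −0.55 ± 0.70 (1.15), a difference within counting error, with IFITM1 at −0.60 and IFI6 at 0.85. The mitochondrially encoded genes did not stand apart (median 0.11 ± 0.24), with 4 of 7 above 0. Single genes moved in opposite directions. MT-CO1 (588 RPKM without and 454 with the drug) and MT-ND5 (293 and 190.5) were lower. MT-ND4L (150 and 339), MT-ND6 (564 and 911) and MT-ATP8 (368 and 666) were higher. For each of these genes the counting intervals of the 2 levels did not overlap.

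OR4D2, an olfactory receptor (3.42), GDF2, a ligand of the BMP family (3.37), and ASB11 (3.98) were among the highest with erythromycin in the mutant. SERPINB10, a protease inhibitor, had 1 read without and 186 with the drug in the mutant, against 2 and 0 in wild type. DUXAP10, a transcribed pseudogene (chromosome 14, 19298697 to 19337669), was at 18121 RPKM without and 90.6 with the drug (−7.68 [−8.10, −7.32]). ZNFX1, a helicase of antiviral defence (−5.17), RASD1, a small GTPase (−4.48), KAT7, a histone acetyltransferase (−3.00), and COMMD3 (12 and 3 reads, −2.56 [−5.24, −0.88]) were also lower. The most-read transcripts in the mutant without erythromycin were DUXAP10 (6934 reads), MROH9 (6590), ACIN1 (6330), ZNFX1 (6010) and ZNF107 (5581), ahead of EEF1A1 (4962). EEF1A1 led the other libraries, with USP7 (8379) next in the mutant with the drug. MROH9, ACIN1 and ZNF107 were chosen after their values were seen. Whether such reads pile up at single positions was not analysed. In this arm 598 genes were at least 2-fold higher and 326 lower, where counting noise alone gave 417 on average and 485 at most. The total of 924 ranged from 174 with at least 20 reads expected to 2922 with no filter. In thinned reads it was 1097, against 1096 in wild type, so the larger total in the mutant was not seen at equal depth. Thinning adds counting noise, and its share at that depth was not simulated, so this cannot show that depth explains the larger total. With at least 20 reads expected the totals were 65 in wild type and 174 in the mutant. Matched also on coding length and GC content, the cytoskeleton and interferon lists of the 7 still stood apart, cholesterol synthesis (0.17, 98.8) then stood apart as higher and extracellular matrix (−0.27, 1.10) as lower, and in thinned reads the interferon (13.4), synthetase (3.41) and G2 and M phase (2.82) calls ended.

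Over both genotypes, a small group of genes rose with erythromycin, among them an ion channel, a growth factor and an olfactory receptor. In limma's additive model 12 of 9612 genes passed at an adjusted p of 0.05, and 12 of 12 rose. TRPV2, a cation channel, rose by 2.43 (log2, adjusted p = 0.00634), with 69.1 and 287 RPKM in wild type and 98.0 and 723 in the mutant. GDF2 rose by 2.74 (adjusted p = 0.00707), OR4D2 by 2.67 (0.00707) and TMEM253 by 2.05 (0.00707). ST7 (1.68), TMEM178B (1.80), the beta-defensin DEFB118 (1.80), the cytokine IL1A (2.01), CEACAM3 (2.07) and MTRNR2L13 (2.20, with 1 and 5 reads in wild type and 3 and 22 in the mutant) also rose. CACNG8, an auxiliary subunit of glutamate receptors (2.62), and the forkhead factor FOXN2 (2.19) completed the 12, and both were chosen after their values were seen. The lowest genes in both genotypes did not pass. They included NANOS3, a germ cell RNA-binding protein (−1.21 in wild type and −1.23 in the mutant, adjusted p = 0.126), the interferon-induced IFITM2 (−1.31 and −0.83), the pluripotency factor SOX2 (−0.76 and −1.06) and the tubulin gene TUBB4A (−1.13 and −0.85). The remaining lowest genes were C6orf226, GMIP, HIST1H1T, MECR, RASL10B and SAMD9.

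Among the lists, 0 genes passed for erythromycin over all genes tested. Adjusted over the list alone, 1 of the 7 mitochondrially encoded genes (MT-CO1 fell by 0.70, adjusted p = 0.0443), 2 of 23 cholesterol synthesis genes (INSIG1 rose by 0.79 and IDI1 by 0.77) and 2 of 48 histones (HIST1H3J fell by 1.82 and HIST1H4I by 1.81) passed. IDI1, HIST1H3J and HIST1H4I were chosen after their values were seen. A total of 43 genes were at least 2-fold higher in both genotypes, where 10.3 would be by chance if the arms were independent, and 18 were at least 2-fold lower, where 5.02 would be. Counting noise alone gave at most 9 and 11. Of the 43 genes, 15 were also at least 2-fold higher in the mutant in both treatments, so what stays open for that set holds for them too. With no term for genotype, and with no variance trend, limma passed 0 genes, and with no filter it passed 149. The number of genes at an unadjusted p under 0.05 was 540 with the additive model, 242 with no term for genotype and 500 with no variance trend.

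The comparison of mutant with wild type cells asked how footprint levels differ with altered RPL4, with and without the drug. Heat-shock genes were lower in the mutant. Their median was −0.48 ± 0.13 without erythromycin (16 of 19 below 0, percentile 0) and −0.84 ± 0.11 with it (18 of 19, percentile 0). BAG3, a partner of HSP70 chaperones, fell by 1.501 over both treatments (adjusted p = 0.0159), with 52.7 and 53.2 RPKM in wild type and 17.2 and 19.2 in the mutant. Of the 19 genes, 1 fell over all genes tested and 10 fell adjusted over the list alone, including HSPA8 (−0.88), HSP90AB1 (−0.83) and HSP90AA1 (−0.66). The chaperonin that folds actin and tubulin (14 genes with prefoldin) was lower too, at −0.31 ± 0.072 (percentile 2.5) and −0.55 ± 0.11 (0.08), with 0 falling over all genes and 7 adjusted over the list alone, CCT7 (−0.54) and CCT3 (−0.54) among them. With coding length and GC content matched as well, the chaperonin list no longer stood apart, at percentiles 4.29 and 3.19. Without the drug its call also ended with a pseudocount of 5 RPKM (2.56), under both scalings by a sum (2.51) and in thinned reads (3.13).

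Small-subunit ribosomal proteins, aminoacyl-tRNA synthetases and ribosome biogenesis factors stood apart as lower in the mutant in both treatments. Large-subunit proteins and initiation factors did so with erythromycin, though for neither did the difference between the responses of the genotypes stand apart (percentiles 4.07 and 8.53). Matched also on coding length and GC content, that difference stood apart for large-subunit proteins (1.25) and not for initiation factors (35.1). Small-subunit ribosomal proteins (32) were at −0.29 ± 0.032 without (percentile 0.45) and −0.44 ± 0.037 with erythromycin (0.03). RPS10 fell over all genes tested (−0.59, adjusted p = 0.0452, chosen after its values were seen), and 18 fell adjusted over the list alone, RPS19 (−0.49), RPS4X (−0.43) and RPS15 (−0.30) among them. Large-subunit proteins other than RPL4 (44) were at −0.22 ± 0.034 (15.1) and −0.37 ± 0.032 (0.58), with 0 over all genes and 9 falling adjusted over the list alone, such as RPL38 (−0.44). Aminoacyl-tRNA synthetases were at −0.26 (1.42) and −0.48 (0.1), and ribosome biogenesis factors at −0.17 (1.13) and −0.40 (0), in which 0 genes passed either way. Initiation factors (36) were at −0.13 (34.6) and −0.36 (0.56), and the latter did not stand apart when coding length and GC content were matched (11.1). Elongation factors (9) were at −0.28 (7.53) and −0.38 (9.25), quality control factors (18) at −0.10 (24.5) and −0.09 (32.6), with the latter turning positive scaled to a common sum, and nonsense-mediated decay factors (14) at 0.13 (85.9) and −0.01 (57.3). The last of these medians turned positive under each of the 3 other scalings, and the mean was above 0. The ribosome biogenesis call without the drug ended with a pseudocount of 5 RPKM (2.64), a mean of at least 1 RPKM (2.92) and no filter (3.28). In thinned reads the large-subunit call (4.71), the initiation call (8.14) and the synthetase call without the drug (8.70) ended, and with at least 20 reads expected so did the large-subunit call (2.62).

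**Figure D2:**
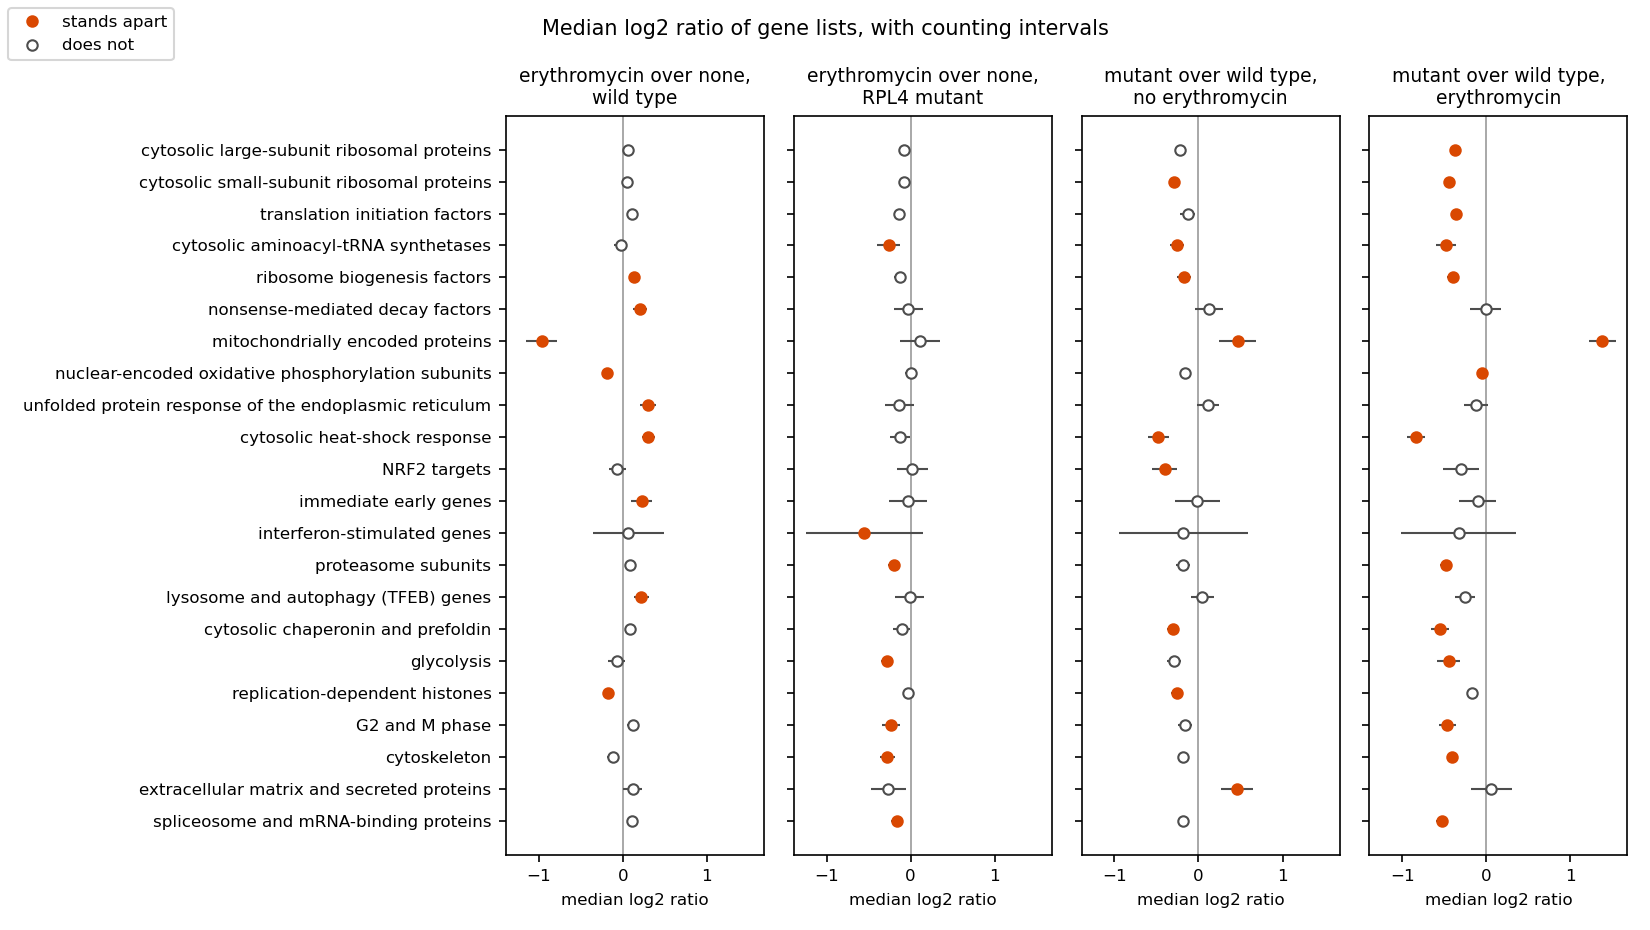
Median log2 ratio (horizontal axes) of each gene list that stood apart in at least 1 of the 4 comparisons, with lines for 95% counting intervals. Filled points mark lists that stand apart from random lists matched on expression, such as heat-shock genes at 0.30 with erythromycin in wild type and at −0.48 and −0.84 in the mutant comparisons.

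Mitochondrially encoded genes were higher in the mutant, at 0.47 ± 0.22 without erythromycin (percentile 99.96) and 1.38 ± 0.16 with it (100). MT-CO1 rose by 1.13 over both treatments (adjusted p = 0.023), MT-ND6 by 1.15 (0.0357) and MT-ND5 by 1.08 (0.0385). These 3 rose over all genes tested and 6 of 7 rose adjusted over the list alone, with MT-ND4L the exception at 0.05. MT-ND4L was lower in the mutant without the drug (−1.04 [−1.67, −0.47]) and higher with it (1.12). Among 76 mitochondrial ribosomal proteins, which did not stand apart, MRPL35 rose by 2.57 (adjusted p = 3.34e-05), from 294 and 489 RPKM in wild type to 2115 and 2452 in the mutant. Nuclear-encoded oxidative phosphorylation subunits were at −0.16 without the drug (40.6) and −0.05 ± 0.06 with it (99.6), where the sign of the latter turned positive under each of the 3 other scalings. NDUFA3 of complex I rose by 0.90 (adjusted p = 0.0349, chosen after its values were seen). Mitochondrial chaperones (12) did not stand apart, though HSPD1 (−0.69) and HSPE1 (−0.72), which the heat-shock list also holds, fell adjusted over the list alone.

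Of 5 other groups, most members were lower in the mutant in both treatments. Among lists matched on expression these groups stood apart with erythromycin and not without it. The difference between the responses of the genotypes did not stand apart for glycolysis (percentile 5.7) and cytoskeleton genes (11.4). It did for proteasome (0.92), spliceosome (0.04) and G2 and M phase genes (0.39). With coding length and GC content matched, it did for G2 and M phase genes alone (1.99), whose call ended in thinned reads (3.93). Proteasome subunits were at −0.19 (26 of 30 below 0, percentile 19.2) without the drug and −0.48 ± 0.071 (percentile 0) with it. Spliceosome and mRNA-binding proteins were at −0.19 (26 of 32, 18.9) and −0.53 ± 0.068 (0), and G2 and M phase genes at −0.16 (18 of 24, 12.9) and −0.47 ± 0.10 (0.03). Glycolysis was at −0.29 (13 of 15, percentile 2.53, or 2.48 with coding length and GC content matched) and −0.45 ± 0.14 (0.65), and cytoskeleton genes at −0.19 (20 of 23, 19.8) and −0.40 ± 0.07 (0.49). ENO1, the enolase of glycolysis, fell by 0.75 over both treatments (adjusted p = 0.035), and adjusted over the list alone 4 of 15 glycolysis genes fell. HNRNPK (−0.80) and TUBB (−0.62), chosen after their values were seen, fell adjusted over the lists of mRNA-binding proteins and cytoskeleton alone, and 0 genes of either list passed over all genes. NRF2 targets (13), which counter oxidants, were at −0.40 ± 0.14 without the drug (0.12) and −0.30 ± 0.21 with it (11.6), and histones at −0.26 ± 0.059 (0.485) and −0.17 ± 0.052 (60.4), where the latter stood apart when coding length and GC content were matched (0.885). HMOX1, the heme-degrading enzyme of the NRF2 list, fell adjusted over the list alone (−0.94, adjusted p = 0.0233) and not over all genes (0.0956). HIST1H3I fell by 3.05 (adjusted p = 7.84e-05), the lowest in this fit among the genes named by rule, and adjusted over the list alone 4 histones fell and 1, HIST1H4J, rose (0.87, chosen after its values were seen). Extracellular matrix and secreted proteins (14) were higher without the drug, at 0.46 ± 0.19 (99.6; SERPINH1 0.44, SPARC 0.17 and TIMP1 −0.34), and did not stand apart with it (0.06). The histone call ended with a mean of at least 20 RPKM (2.83) and with at least 20 reads expected (19.6), and the glycolysis call ended when coding length and GC content were matched (4.30).

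A set of genes, many but not all with few footprints in wild type cells, was higher in the mutant. In limma's model 123 of 9612 genes passed, of which 115 rose and 8 fell. ST7 (chromosome 7, 116953327 to 117223907) rose by 3.89 (SE 0.223, adjusted p = 2.13e-05), with 19.8 and 60.5 RPKM in wild type and 283 and 1007 in the mutant. USP7, a deubiquitinase that acts on MDM2 and p53 (chromosome 16, 8892094 to 8963484), rose by 3.78 (adjusted p = 2.13e-05), from 97.53 and 131 to 973 and 2549 RPKM. The beta-defensin DEFB118 (3.75, adjusted p = 3.1e-05), the glial filament gene GFAP (4.03, 0.000207), NANOS3 (3.21, 3.19e-05) and KLHL10 (3.23, 0.000207) rose as well. FUT8, which adds core fucose to glycans (3.37), and CLIC2 (3.41) also rose, as did MTRNR2L8 (4.55, from 1 and 4 reads to 15 and 15) and MTRNR2L13 (3.52). Besides HIST1H3I, BAG3, ENO1, RPL4 and RPS10, the genes that fell were LRRC6, which assembles dynein arms (−1.71, 0.0113), CMC2 of cytochrome c oxidase assembly (−1.29, 0.0469) and CCDC82 (−1.61, 0.0385, chosen after its values were seen). CMC2 had 62 and 45 reads in wild type and 4 and 9 in the mutant, and its interval with erythromycin included 0 [−2.24, 0.03]. HIST1H3I had 195 and 100 reads in wild type and 5 and 4 in the mutant. The lowest genes in both treatments that did not pass were ACSL4, CITED2, EAF1, HMOX1, PPIL3 and RAB3B. At least 2-fold, 214 genes were higher in the mutant in both treatments, where 35.7 would be by chance if the treatments were independent, and 16 were lower, where 7.20 would be. Counting noise alone gave at most 13 and 15. The median level of the 214 was 5.76 RPKM in wild type and 19.8 in the mutant without the drug, and 5.6 and 22.6 with it. With no term for treatment 54 genes passed (52 higher and 2 lower), with no variance trend 65 (63 and 2), and with no filter 441 (311 and 130).

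**Figure D3:**
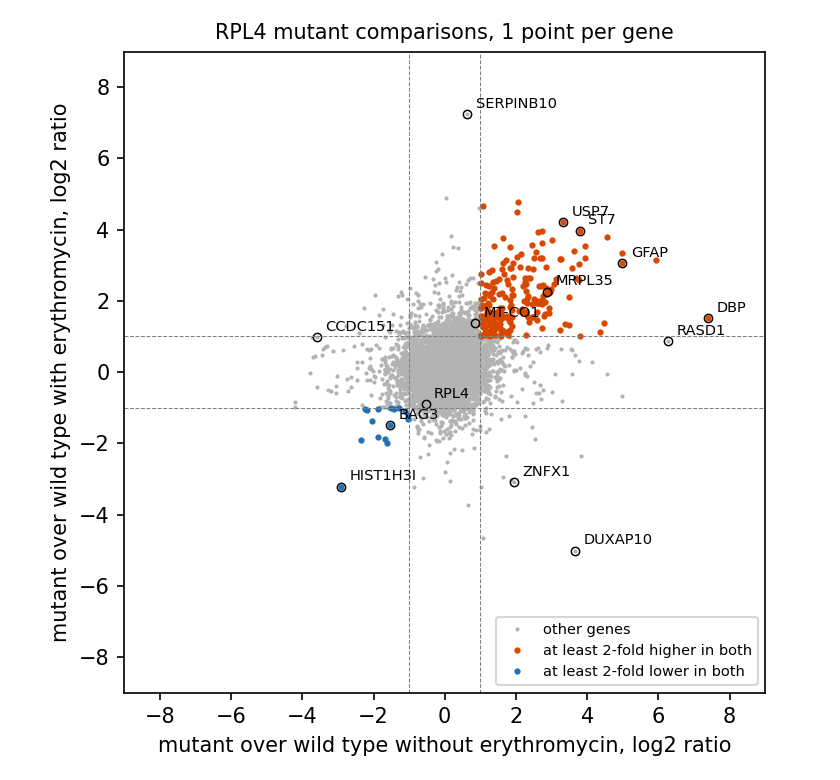
Log2 ratio of mutant over wild type without (horizontal axis) and with erythromycin (vertical axis), 1 point per gene with a mean of at least 5 RPKM, and dashed lines at 2-fold. The 214 genes at least 2-fold higher in both comparisons outnumber the 16 at least 2-fold lower in both, and ST7 lies at 3.80 and 3.97.

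Without erythromycin DBP was the highest in the mutant (7.39 [7.11, 7.79]), at 25.5 RPKM in wild type and 4359 in the mutant, followed by RASD1 (6.28), MTRNR2L8 (5.94, from 1 read to 15), GFAP (4.99) and MTRNR2L12 (4.37, from 1 read to 5). CCDC151 (−3.59), HIST1H3F (2 reads in the mutant, −3.19 [−6.40, −1.45]), HIVEP3 (−3.05), the olfactory receptor OR11L1 (−3.01) and HIST1H3I (−2.90) were the lowest. With erythromycin the highest in the mutant were SERPINB10 (0 reads in wild type and 186 in the mutant), the zinc finger gene ZNF117 (4.77), LGALS4, a galectin of the gut (4.60), USP7 (4.21) and ST7 (3.97). The lowest were DUXAP10 (−5.01), HIST1H3I (−3.22), ZNFX1 (−3.09), BBIP1 of the ciliary BBSome (2 reads in the mutant, −2.53 [−5.81, −0.73]) and COMMD3 (3 reads in the mutant, −2.12 [−4.67, −0.66]). At least 2-fold, 508 genes were higher and 319 lower without the drug, and 675 higher and 217 lower with it. Counting noise alone gave at most 333 and 168. Scaled to a common sum, which shifts the median gene by 0.14 with erythromycin, 86.2% of the latter genes were higher in place of 75.7%. The totals of 827 and 892 ranged from 188 and 265 with at least 20 reads expected to 2458 and 2218 with no filter.

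The difference between the responses of the genotypes asked whether the mutation changes the effect of the drug. For mitochondrially encoded genes the mutant response was higher than the wild type response by 0.94 ± 0.27 (percentile 100), with 6 of 7 above 0, MT-CO2 at 1.38 and MT-ND5 at −0.21. For nuclear-encoded oxidative phosphorylation subunits it was higher by 0.15 ± 0.083 (99.9). Heat-shock genes went the other way, at −0.47 ± 0.13 (0.04), with 0.30 in wild type (percentile 100) and −0.13 in the mutant (13.3). The unfolded protein response (−0.32, 1.18; CALR −0.72, SEC61B 0.14), spliceosome proteins (−0.33, 0.04), G2 and M phase genes (−0.35, 0.39), extracellular matrix (−0.38, 2.02), immediate early genes (−0.34, 1.57), proteasome subunits (−0.25, 0.92) and ribosome biogenesis factors (−0.22, 1.28; NPM1 −0.76, NOP10 0.12) were also lower. None of these differences was tested, because no group had a replicate. In thinned reads the heat-shock (3.29), unfolded protein (11.3), G2 and M phase (3.93), extracellular matrix (24.3) and ribosome biogenesis (7.47) lists no longer stood apart, and a mean of at least 20 RPKM ended the calls on immediate early genes (8.10), extracellular matrix (4.40) and ribosome biogenesis (4.80). Immediate early genes also fell short with a pseudocount of 5 RPKM (2.80) and with at least 20 reads expected (12.2), and matching on coding length and GC content ended the calls on ribosome biogenesis (4.18), unfolded protein (3.84), proteasome (13.9) and spliceosome genes (4.37).

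Among single genes, SERPINB10 (6.63), CCDC151 (4.60), LGALS4 (3.66), CREG2 (3.37) and GSDMB, a pore-forming gasdermin (3.30), had the highest difference of responses. DUXAP10 (−8.66), DBP (−5.86), RASD1 (−5.40), ZNFX1 (−5.00) and IGSF22 (−4.07) had the lowest. CREG2 was at 967 and 484 RPKM in wild type and 415 and 2262 in the mutant. GSDMB was at 140 and 113 in wild type and 163 and 1365 in the mutant. At least 2-fold, 802 genes were higher and 536 lower, where counting noise alone gave 596 on average and 658 at most. The total of 1338 ranged from 299 with at least 20 reads expected to 3697 with no filter.

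Across genes, the mutant effect without erythromycin tracked that with it, while the drug responses of the genotypes hardly tracked each other. Over 9612 genes, which are not independent replicates, the mutant effects had a Pearson r of 0.312 and a Spearman rho of 0.251. The erythromycin responses had an r of 0.039 and a rho of 0.0284, within the 0.055 that counting noise alone reached. ST7, GDF2 and TRPV2 were among the genes that moved alike in both arms, and DBP, IGSF22 and CCDC151 among those that did not. The mean erythromycin effect and the mean mutant effect had an r of 0.0557 and a rho of 0.00567, and counting noise alone gave −0.24 on average for this pair. At 100 RPKM or more (1721 genes) r was 0.0689 for the drug, 0.52 for the mutant and 0.272 between the mean effects. With a mean of at least 1 RPKM and with no filter, the last r turned negative, at −0.00968 and −0.00503. With no filter the r of the drug responses was 0.00964 and that of the mutant effects 0.173.

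With random lists matched on expression, groups that did not stand apart in any comparison included targets of ATF4 in the integrated stress response (24 measured; MTHFD2, PHGDH), p53 targets (22; BAX, CDKN1A), hypoxia targets (12), S phase genes (33; PCNA, TYMS), cholesterol synthesis (23; FDFT1), signal recognition and translocation factors (29; SRP14), nascent-chain factors (10; BTF3), MYC targets (12), neuron-type genes (11; STMN1) and ribosome-associated quality control factors (18; EDF1). For the mutant, 0 genes of the quality control list passed over all genes and 2 fell adjusted over the list alone, the ribosomal scaffold RACK1 (−0.64) and the segregase VCP (−0.85). In the hypoxia list ADM (−1.21, chosen after its values were seen) fell and ANKRD37 (1.48) rose adjusted over the list alone, and in the MYC list LDHA (−0.55) and HSPD1 (−0.69) fell. EGR2, an immediate early gene, rose over all genes tested (1.96, adjusted p = 0.0256, chosen after its values were seen). Of 35 lists, 9, 7, 9 and 14 stood apart in the single differences in the order given here and 10 in the difference of responses, where about 1.8 would by chance.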

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

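Of the tests in this part, the counting-noise tests of the genes higher in the mutant and of the mitochondrially encoded genes, and the test of an even background, were chosen only after the results were seen.

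These results stood out because the erythromycin response had opposite signs in wild type and mutant cells. The differences were not tested, since each group has 1 library. For lists, the mutant response minus the wild type response was −0.22 for ribosome biogenesis factors (0.13 in wild type, −0.13 in the mutant), −0.47 for heat-shock genes (0.30, −0.13), −0.25 for proteasome subunits (0.09, −0.20), −0.35 for G2 and M phase genes (0.12, −0.23), −0.38 for extracellular matrix genes (0.12, −0.27) and −0.33 for spliceosome and mRNA-binding proteins (0.10, −0.17). In thinned reads the biogenesis (percentile 7.47), heat-shock (3.29), G2 and M phase (3.93) and extracellular matrix (24.3) lists no longer stood apart, and matched on coding length and GC content neither did biogenesis (4.18), proteasome (13.9) and spliceosome genes (4.37). Among random lists matched on expression, none of these lists stood apart in the responses of both genotypes. Heat-shock (percentile 13.3) and biogenesis (6.29) genes did not in the mutant. Proteasome (91.7), G2 and M phase (93.3) and spliceosome genes (95.55) did not in wild type. Extracellular matrix genes did not in either (85.2 in wild type, 4.13 in the mutant). CCDC151 differed by 4.60 (−4.11 in wild type, 0.48 in the mutant), CREG2 by 3.37 (−0.98, 2.39) and GSDMB by 3.30 (−0.29, 3.01). DUXAP10 differed by −8.66 (0.98, −7.68) and IGSF22 by −4.07 (3.16, −0.91).

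A total of 214 genes, many with few footprints in wild type, were at least 2-fold higher in the mutant both without and with erythromycin. Counting noise of the shallow mutant libraries reached at most 13 such genes in simulated draws. A background spread evenly over transcripts would also cover the 122 listed members of receptor, defensin and keratin-associated families, where the upper quartile of the gain was 1.26 RPKM without the drug against a median gain of 14.3 RPKM for the set, but the pooled level of the families was 7.54 RPKM in wild type and 16.6 in the mutant, and 10.0 and 53.2 with it, so gains of a few members stay open. Few of the genes, 1.40%, share 24 bases with small structured RNAs or mitochondrial ribosomal RNA, against 0.916% of all tested genes. Mature 18S and 28S ribosomal RNA, their precursors and reads piled at single positions were not searched, and these, like an effect of the mutation itself, stay open and untested.

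The 7 measured mitochondrially encoded genes were lower with erythromycin in wild type cells. Counting noise is argued against, since 7 of 7 counting intervals lay below 0. A trend with expression, coding length and GC content is argued against too, since the median went from −0.96 to −1.05 once genes alike in these properties were subtracted. An effect of the drug and spread between cultures stay open and untested, because no group has a replicate. In the mutant the list's median with the drug was 0.11 ± 0.24, where MT-CO1 and MT-ND5 were lower and MT-ND4L, MT-ND6 and MT-ATP8 higher.

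Heat-shock genes were lower in the mutant. Subtracting genes alike in expression, coding length and GC content moved the median with erythromycin from −0.84 to −0.57, so such a trend may carry part of that difference but not all of it. Without erythromycin the median went from −0.48 to −0.355, short of the limit set for the comparison with the drug, and 16 of 19 genes were below 0 after subtraction. Among random lists matched on expression, coding length and GC content, chosen after the results were seen, the list without erythromycin lay at percentile 0. These values argue against such a trend as the whole of that difference, while it may carry part of it. An effect of the mutation, or of how the lines were made, stays open and was not tested.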

How the results depend on the processing

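Thinned reads, the filter on 20 reads expected, the fit with no variance trend and random lists matched on coding length and GC content were chosen only after the results were seen. Of the recomputed main results, 35 stayed within their limits, 58 moved and 2 changed sign. The counts of genes at least 2-fold different are given in the order erythromycin in wild type, erythromycin in the mutant, mutant without and mutant with the drug, and difference of responses. With a pseudocount of 5 RPKM they were 114, 477, 409, 457 and 758. With a mean of at least 1 RPKM they were 697, 1981, 1860, 1671 and 2549, with a mean of at least 20 RPKM 107, 266, 254, 310 and 439, and with no filter 925, 2922, 2458, 2218 and 3697, where more or fewer genes are counted. With at least 20 reads expected they were 65, 174, 188, 265 and 299. Thinned to the shallowest library, they were 1096, 1097, 1182, 1445 and 2092. At this equal depth the counts with erythromycin were thus alike in wild type and mutant, unlike the 314 and 924 reported. Counting noise at this depth was not simulated, so the likeness cannot show that depth explains the difference.

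Correlations across genes are given in the order drug responses, mutant effects, and mean drug with mean mutant effect. The last 2 were 0.284 and 0.00778 with a pseudocount of 0.1 RPKM, 0.338 and 0.1 with 5 RPKM, 0.417 and 0.19 with a mean of at least 20 RPKM, and 0.214 and 0.113 in thinned reads. All 3 were 0.0154, 0.212 and −0.00968 with a mean of at least 1 RPKM, 0.00964, 0.173 and −0.00503 with no filter, and 0.064, 0.456 and 0.177 with at least 20 reads expected. The last r thus turned negative with the looser filter and with none, and the cause was not tested.

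limma passed 31 genes for erythromycin and 209 for the mutant with a pseudocount of 0.1 RPKM, 62 and 290 with a mean of at least 1 RPKM, 149 and 441 with no filter, 26 and 194 without centring, and 80 and 267 with at least 20 reads expected. With a mean of at least 20 RPKM 40 passed for erythromycin. Of the 12 reported, 11 were among these 40, 8 among the 80 with at least 20 reads expected and 7 among the 15 that passed in thinned reads. For erythromycin 0 passed with no term for genotype and with no variance trend, with 242 and 500 genes at an unadjusted p under 0.05. For the mutant 54 passed with no term for treatment and 65 with no variance trend, and 54 of each were among the 123 reported. The causes were not tested.

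The median of nuclear-encoded oxidative phosphorylation subunits in the mutant with erythromycin, −0.05 as reported, was 0.0659 with a mean of at least 20 RPKM, 0.0661 with at least 20 reads expected, 0.0161 without centring, 0.0922 scaled to a common sum and 0.0148 scaled by the sum of other genes. For the scalings the shift of all genes shows the cause, and for the filters the cause was not tested. Lists that stood apart still did so in 457 of 488 recomputations, and in 36 of 49 comparisons when random lists were matched also on coding length and GC content, which added 5 others. The 488 include no centring and the scalings by a sum, which shift a list and its random lists almost alike. Those recomputations could hardly end a call, so the share of 457 overstates how firm the calls are. Depth limits the mutant libraries most, where a median of 23 reads per tested gene without the drug leaves wide intervals.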

Other observations

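None of the values in this part is a planned comparison, and the tests of them, the counting-noise limits, were chosen only after the results were seen.

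The 214 genes at least 2-fold higher in the mutant in both treatments took 1.21% and 1.5% of reads in wild type without and with erythromycin, and 7.55% and 8.15% in the mutant. Of the 43 genes at least 2-fold higher with erythromycin in both genotypes, 15 were among these 214. Genes of families with restricted expression (olfactory, taste and vomeronasal receptors, keratin-associated proteins and defensins) took 0.0817% and 0.109% of reads in wild type and 0.180% and 0.577% in the mutant. OR4D2 alone made up 14.9% and 42.0% of these reads in wild type, and 13.5% and 47.1% in the mutant. Mitochondrially encoded genes took 0.144% and 0.0816% of reads in wild type, and 0.229% and 0.224% in the mutant.

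Few markers of other cell types were measured. Of the fibroblast list 1 gene was measured, COL1A1 at 6.68 and 4.10 RPKM in wild type and 6.40 and 3.89 in the mutant. Of the blood cell list 1 gene was measured, CORO1A at 9.73, 11.9, 9.55 and 7.26 RPKM in the same order. Of the keratinocyte list 3 genes were measured, with DSP at 21.4, 16.7, 21.9 and 19.6 RPKM, SFN at 25.3, 23.1, 19.9 and 22.9 and KRT17 at 1.04, 4.82, 15.3 and 3.10. Of the hepatocyte list 0 genes were measured.

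Each library held genes that stood at least 2-fold above or below all 3 others. The numbers above and below were 16 and 74 in wild type without erythromycin, 17 and 38 in wild type with it, 86 and 130 in the mutant without it and 170 and 63 in the mutant with it. Counting noise alone reached at most 7 and 6, 8 and 10, 23 and 152, and 13 and 59. In the mutant without erythromycin the 130 genes below thus lay within what counting noise reached.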
